A study of Glycine max with 24 samples.

How the data were processed

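The deposited table held log2 intensities, per the labels from biotin-labelled total RNA hybridised to 1-colour Affymetrix soybean arrays. Each row is a probe set, a group of short probes read as 1 transcript. The table had 24 arrays and 37653 probe sets, of which 37593 were soybean probe sets and 60 were control probe sets. The submitters' notes name RMA, GCRMA and limma, with no role, order or version; how the probes were summarised is not given in the sources used here. The values themselves were not the output of RMA or GCRMA as those are usually made: on the linear scale 99.65% of them were whole numbers within 0.01, and array medians ran from 7.00 to 8.04 on the log2 scale. No background estimate came with the values, so how far dim probe sets lie above background is unknown. No pair of columns was identical (0 pairs), and the highest correlation between any pair of arrays was 0.991.

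The plan written before the data were examined used the deposited values without further scaling, with quantile normalization as an alternative. Because the array medians differed, quantile normalization of the soybean probe sets (limma, normalizeQuantiles) was made the main choice after the data were examined, and the unscaled values became the alternative. Group means of the 8 groups were then fitted with limma, with its moderated variance (prior degrees of freedom 3.65, residual degrees of freedom 16). Benjamini-Hochberg adjustment was made within each of 12 contrasts, with a threshold of 0.05 and no minimum fold change. Standard errors are those of the moderated model. R 4.3.3 and limma 3.58.1 were used. Replicates are separate samples per the labels, and whether a sample pools plants is not stated; the p-values measure the spread between these samples, which may be technical.

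The contrasts were the aphid effect (infested minus uninfested) in each cultivar on each day, the difference between cultivars in that effect on each day (resistant minus susceptible), the difference between days in that effect in each cultivar (day 7 minus day 1), the cultivar difference among uninfested leaves on each day (resistant minus susceptible), and the day difference among uninfested leaves in each cultivar (day 7 minus day 1). Log2 differences are written with their standard error, and n is 3 arrays per group throughout.

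Probe sets were tied to genes by the platform annotation supplied with the data. In it 8677 soybean probe sets had 1 gene, 370 had several and 28546 had none. The identifiers of 8652 probe sets were found in the RefSeq gene table of Glycine_max_v4.0, and 0 symbols needed updating. An informative name, meaning a symbol or synonym other than a locus number, was available for 1882 probe sets of 1131 genes. Most called probe sets therefore have no gene name here.

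Genes were named by a rule fixed before the data were examined. For each aphid effect, among probe sets with 1 informatively named gene that passed an adjusted p of 0.05 and whose 3 infested arrays all lay above or all lay below the 3 uninfested ones, it took the 10 largest rises and 10 largest falls, with 1 probe set per gene. Where none passed, it took the 5 genes with the smallest p as values. For the cultivar difference it took up to 10 rises and 10 falls with the same sign on both days, and for each interaction the 5 genes with the smallest p. Each called gene list added up to 2 members above and 2 below 0 with the smallest p. A named gene's value is that of 1 probe set, and the gene's other probe sets may not have passed. Other names were chosen after their values were seen: 1 unnamed probe set, LOC100526921, members that passed or stood out in lists, and genes repeated across contrasts.

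Alternatives tried were median centring, no scaling, normexp background correction with an offset of 50, only the 18810 probe sets above a mean of 7.62, all probe sets of the array, a trended and robust variance, array weights, a replicate block, a 2-fold minimum, fits of a contrast's own groups, the 3' minus 5' signal of the control probe sets as a covariate, and leaving out each array or the 3 least like the others. The normexp and covariate fits and the fit without 3 arrays were chosen after seeing the data; the unscaled fit is the planned main one, made an alternative after seeing them.

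Gene lists were tested with camera in limma at its preset correlation of 0.01, against the other informatively named genes, with 1 probe set per gene (that of highest mean) and at least 3 members. Of 27 lists fixed before the data were examined, 15 could be tested: jasmonate synthesis, jasmonate response, salicylate and pathogenesis-related (PR) proteins, ethylene, abscisic acid, phenylpropanoid entry, flavonoids and isoflavonoids, WRKY factors, NAC and MYB factors, peroxidases and redox, fatty acid desaturation, sugar and amino acid supply, heat shock proteins, root, nodule and seed markers, and phloem and vascular markers. The other 12 had too few members with a name, 8 of them with 0 and 4 with 1 or 2. A further 20 lists were added after the annotation's symbols were read and before any model was fitted. Members were found by symbol or synonym alone, so the jasmonate synthesis list holds any gene named as a lipoxygenase (LOX), whatever its role. List p-values were adjusted over the lists within a contrast. A second camera run estimated the correlation between members from the data. List tests were planned for the aphid effects, the cultivar differences and the differences between cultivars in the aphid effect; those for the day differences were added later.

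The procedure was tried on simulated arrays. These were drawn from each probe set's real mean and spread as independent random noise, with no structure shared within an array. Some probe sets were then raised or lowered in the infested susceptible arrays of day 7. In that aphid effect it called 10 of 67 probe sets changed by log2 0.5, 45 of 67 changed by 1 and 64 of 66 changed by 2. It made 4 false calls among 37363. In the simulated resistant cultivar on day 1, left without added changes, it made 0 calls. Real arrays may share structure, so these are not error rates of the real data.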

Results

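Transcript levels were measured in the third trifoliate leaf of soybean (Glycine max) with and without soybean aphids, phloem-feeding insects. Leaves came from the aphid-susceptible cultivar SD01-76R and the aphid-resistant cultivar LD05-16060, after 1 or 7 days, in a growth chamber at 25 C with 16 h of light. Per the labels, each infested plant received 30 aphids, 10 on each leaflet and at least 21 of them adults, at the V3 stage. Plants were netted, and the aphids were taken off before sampling. The 2 cultivars, 2 treatments and 2 days made 8 groups of 3 arrays, 24 in all. The design asks which transcripts respond to aphids in each cultivar and whether that response differs. The number of arrays limits the precision.

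Array medians of the deposited log2 values ran from 7.00 to 8.04. After quantile normalization, the mean correlation of an array with the others ran from 0.900 to 0.966. Uninfested susceptible leaves of day 1 stood apart on the first principal component (39.6% of the variance), where their 3 arrays scored 109, 69.1 and 75.2. The highest other array, infested resistant day 1 replicate 2, scored 66.2. The 3' minus 5' signal of the control transcripts, a sign of RNA quality, averaged 1.31 ± 0.37 (SD, n = 3) in uninfested susceptible leaves of day 1. In the other groups it averaged between 0.833 and 1.18. It was 1.721, 1.005 and 1.205 on the 3 arrays of that group. The signal is a mean over control transcripts. For 1 of them, SucBP, it was 3.43, 1.69 and 2.05 on these arrays, and 0.339 to 2.83 on the others. Sieve element occlusion genes, markers of phloem, averaged 7.16 ± 0.56 (SD, n = 3) on the log2 scale in that group, against group means of 5.70 to 6.55 elsewhere. Each comparison below that uses this group carries these 3 differences.

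**Figure D1:**
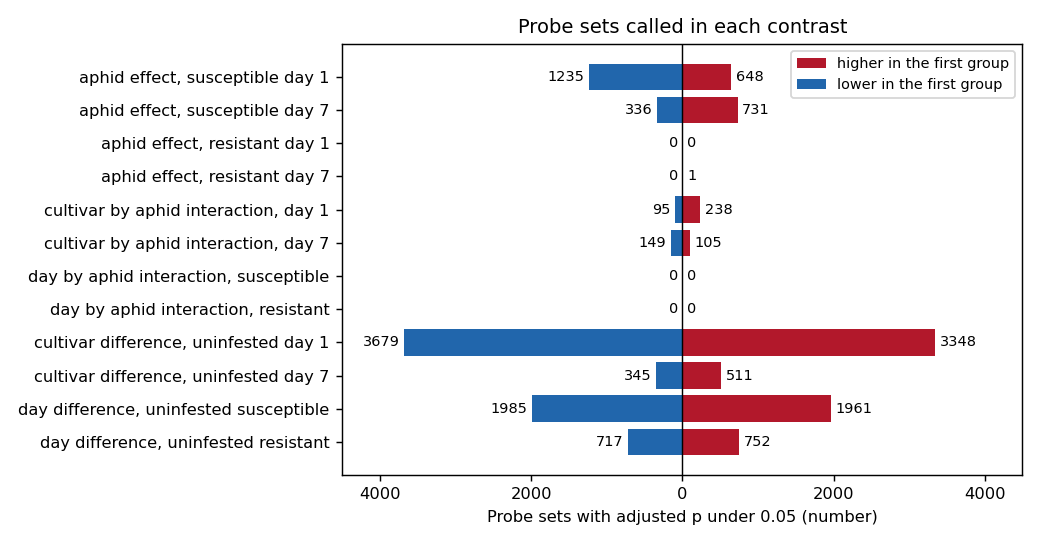
Number of soybean probe sets (horizontal axis) called higher or lower in each of the 12 contrasts (vertical axis) at an adjusted p under 0.05. The cultivar difference on day 1 had 7027 calls, the susceptible cultivar's aphid effect 1883 on day 1 and 1067 on day 7, and the resistant cultivar's 0 and 1.

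In susceptible leaves infested for 7 days, the named genes that rose included PM30, MAT1, PM3, SCOF-1 and ACS1. PM30, a seed maturation protein gene, rose 33.5-fold (log2 5.07 ± 1.11, SE, n = 3 arrays per group, adjusted p = 0.0175). MAT1, whose synonyms name a dehydrin, rose 27.6-fold (4.79 ± 1.16, adjusted p = 0.0297), PM35 rose 9.97-fold (3.32 ± 0.83) and PM3 rose 7.05-fold (2.82 ± 0.46, adjusted p = 0.00277). Regulator genes that rose were the cold-inducible zinc finger gene SCOF-1 by 2.99 ± 0.45 (10.96 ± 0.59 against 7.97 ± 0.55, SD, n = 3), ERF6 of the ethylene response by 2.23 ± 0.51 and NAC1 by 2.18 ± 0.58 log2 units. The rise was called in 1 of 2 probe sets of NAC1 and 3 of 3 of SCOF-1. ACS1, an enzyme gene of ethylene synthesis, rose from 5.45 ± 0.48 to 8.69 ± 0.96 (SD, n = 3, adjusted p = 0.00111), the DREB1-like factor gene from 5.41 ± 0.52 to 9.34 ± 1.51 (adjusted p = 0.0146) and B13-1-9 from 5.46 ± 0.16 to 10.28 ± 0.965 (adjusted p = 0.00053). The uninfested means of these 3 genes lay near the 5th percentile of all values (5.28) and are not shown to be above background, so no fold is given. Those of PM30 (5.92), PM3 (5.92) and NAC1 (5.86) were little higher and are not shown to be above background either. Their folds and differences are therefore not exact sizes.

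The largest falls among named genes on day 7 were those of EXP2, NES and AG1. EXP2, a cell wall expansin gene, fell 4.12-fold (log2 −2.04 ± 0.35, SE, n = 3, adjusted p = 0.0043). The light-harvesting protein gene LHCP (LOC547819) fell 2.24-fold, from 14.31 ± 0.16 to 13.15 ± 0.44 (SD, n = 3, adjusted p = 0.00706), and the aquaporin gene PIP2-4 fell 2.41-fold. LHCP lay far above the 95th percentile of all values (11.16), and the same normalized values recurred on several arrays. Its fold is therefore not an exact size. NES fell by 1.88 ± 0.49, AG1 by 1.87 ± 0.36, SGlu2 (LOC547822) by 1.65 ± 0.44, SSH2 by 1.46 ± 0.37, PK (LOC547791) by 1.00 ± 0.26 and HDL56 by 0.94 ± 0.22 log2 units. The fall was called in 1 of 4 probe sets of HDL56, 1 of 3 of PAL2.1 and 1 of 2 each of PK and PIP2-4. It was called in 3 of 3 of EXP2 and 2 of 2 of LHCP. Of the 7 measured genes of phenylpropanoid entry, PAL2.1, for phenylalanine ammonia-lyase, fell 2.85-fold (−1.51 ± 0.40, adjusted p = 0.0472), 6 did not pass, and 3 fell when adjusted over the list alone. 4CL4 had −1.28 ± 0.45. As a set the list was lower (median −0.75, 0 of 7 above 0, adjusted p = 0.0277), a call lost at adjusted p = 0.839 with an estimated correlation. It was also lost with median centring (adjusted p = 0.0717), and the unscaled median was −0.359. Fatty acid desaturation had a median of −0.56 (adjusted p = 0.0768) and jasmonate synthesis 0.11 (adjusted p = 0.494). In the ethylene list ERF6 rose (1 of 4; adjusted p = 0.894) and in the abscisic acid list MAT1 rose (1 of 4; adjusted p = 0.408).

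On day 7 limma called 1067 probe sets in the susceptible cultivar, 731 higher and 336 lower with aphids. In 24.3% of all probe sets the 3 infested arrays did not overlap the 3 uninfested ones, where chance gives 10%; 1058 of the calls were among them. The balance of directions depended on scaling, with 802 higher and 726 lower after median centring and 2116 higher and 21 lower unscaled, where the median of all probe sets moved by 0.258. The call count was 222 without infested replicate 1, 421 without infested replicate 3, 275 without uninfested replicate 1 and 238 without uninfested replicate 3, while a 3' minus 5' covariate gave 2362. Of the 20 named genes, 18 passed with that covariate, 13 unscaled, and 6 without infested replicate 1 or uninfested replicate 3.

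**Figure D2:**
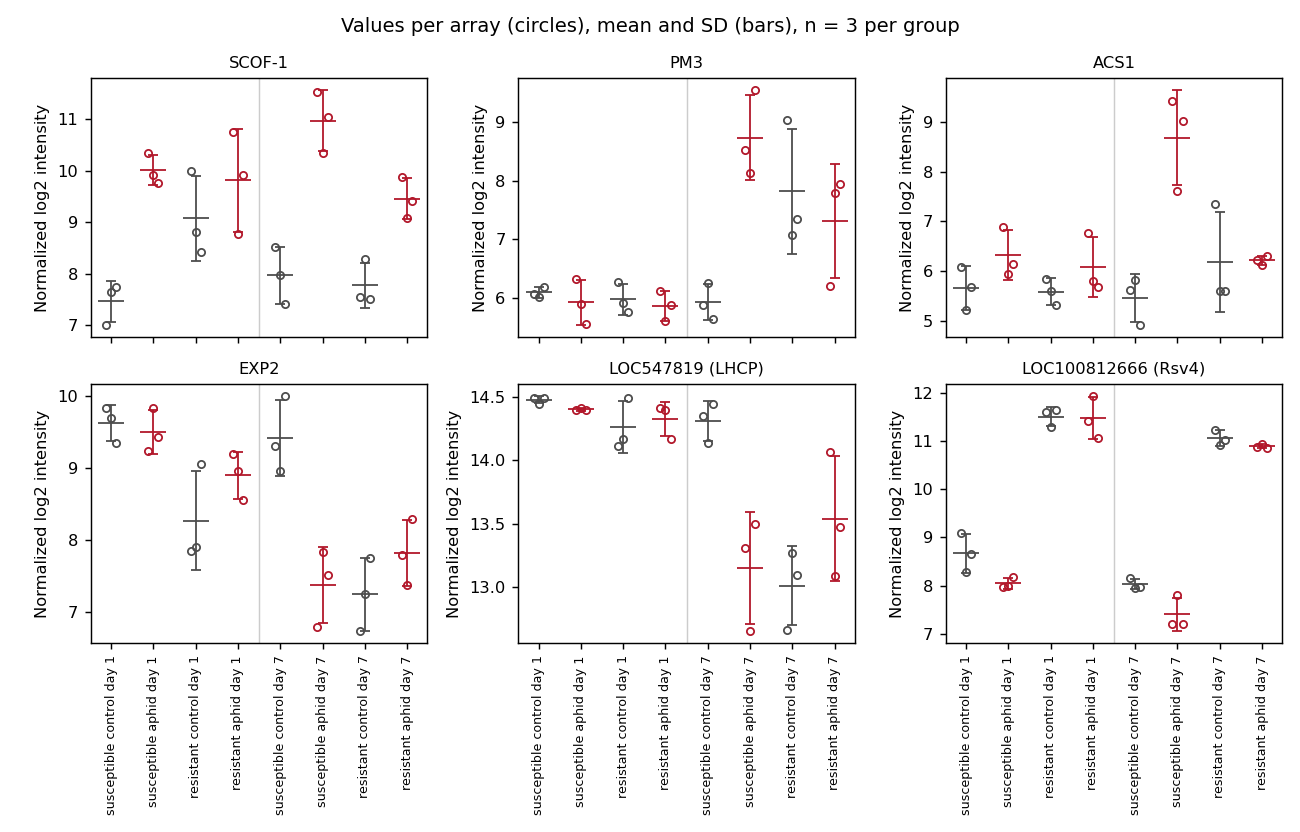
Normalized log2 intensity (vertical axis) of SCOF-1, PM3, ACS1, EXP2, LHCP and Rsv4 on each array of the 8 groups, with the mean and SD of the 3 arrays. SCOF-1 averaged 10.96 in infested and 7.97 in uninfested susceptible leaves of day 7, and Rsv4 differed between the cultivars on both days.

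After 1 day of aphids, the named genes that rose in susceptible leaves included WRKY30, SCOF-1 and APX2, and those that fell included BZIP50, ADR11 and PIP1-6. WRKY30, a WRKY transcription factor gene, rose 8.04-fold (log2 3.01 ± 0.75, SE, n = 3, adjusted p = 0.0326). SCOF-1 rose 5.82-fold (2.54 ± 0.45, from 7.47 ± 0.40 to 10.01 ± 0.30, SD, n = 3) and B13-1-9 rose from 5.47 ± 0.069 to 8.14 ± 0.909 (SD, n = 3, adjusted p = 0.0244), with an uninfested mean near the 5th percentile of all values (5.28) and not shown to be above background. APX2, for an ascorbate peroxidase, rose by 1.44 ± 0.31, CCR by 1.39 ± 0.39 and CYP98A2 by 1.56 ± 0.41 log2 units. The rise was called in 1 of 3 probe sets of APX2, 1 of 2 of CCR, 1 of 6 of CYP98A2 and 1 of 2 of H4. It was called in 2 of 2 of WRKY30 and 3 of 3 of SCOF-1. Phenylpropanoid entry (0 of 7 passed, adjusted p = 0.218) and peroxidases and redox (2 of 39 passed, adjusted p = 0.0894) were not called as sets. H4 rose by 2.34 ± 0.62, PSK5 by 2.12 ± 0.57, PTS-L4 by 1.67 ± 0.48 and the ferritin gene SFERH-2 by 1.48 ± 0.42. BZIP50 fell 9.27-fold (−3.21 ± 0.64, adjusted p = 0.0167), ADR11 fell 9.08-fold (−3.18 ± 0.57) and the aquaporin gene PIP1-6 fell 7.45-fold (−2.90 ± 0.70). Of the others GASA3 fell 5.37-fold and GASA14 5.29-fold, and BZIP48 fell from 8.37 ± 1.13 to 5.76 ± 0.18 (SD, n = 3). That infested level of BZIP48 lay not far above the 5th percentile and is not shown to be above background, so no fold is given. GmTIP2;3 (LOC100306092), an aquaporin gene of the vacuole membrane, fell by 2.22 ± 0.51, SGlu2 by 2.09 ± 0.44 and CYP97C10 by 1.56 ± 0.44. BZIP58 fell from 6.78 ± 1.29 to 5.19 ± 0.306 (SD, n = 3, adjusted p = 0.0301), a level below that percentile, so no fold is given.

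Of 53 WRKY genes on day 1, 3 rose (WRKY22 by 0.66, WRKY51 by 1.10 and WRKY30), 50 did not pass, and 14 rose when adjusted over the list alone. As a set they were higher (44 of 53 above 0, adjusted p = 2.73e-05), a call lost at adjusted p = 0.464 with an estimated correlation. The same p of 0.464 with an estimated correlation applied to the day 1 calls of jasmonate synthesis (median 0.56, 13 of 15 above 0, adjusted p = 0.0382), flavonoids and isoflavonoids (median 1.04, 12 of 13 above 0, adjusted p = 0.0382), fatty acid desaturation (median −0.49, adjusted p = 0.0382) and the phloem markers (median −0.56, 0 of 8 above 0, adjusted p = 0.0182). With median centring jasmonate synthesis was not called (adjusted p = 0.0604), nor was desaturation on unscaled values (adjusted p = 0.0838). In jasmonate synthesis 0 of 15 passed and 2 rose when adjusted over the list alone; LOX10 had 3.42 ± 1.12 (adjusted p = 0.0724). In the flavonoid list 0 of 13 passed, and 0 when adjusted over the list alone; CHR5 had 1.49 ± 0.61. In the desaturation list FAD8.2 fell by 1.44 ± 0.41 (adjusted p = 0.0474), and FAD7-2 had 1.28 ± 0.55 (adjusted p = 0.158); adjusted over the list alone, 1 of 8 rose and 5 fell. Of the 8 phloem markers 0 passed, and 0 when adjusted over the list alone (SEOF −1.27 ± 0.51, adjusted p = 0.129).

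On day 1 limma called 1883 probe sets in the susceptible cultivar, 648 higher and 1235 lower with aphids; in 31% of all probe sets the groups did not overlap (chance gives 10%). Unscaled values gave 105 higher and 46 lower, with a median shift of −0.126. The count was 9 without uninfested replicate 1, 2913 without uninfested replicate 2, 1242 without uninfested replicate 3, and 12, 517 and 490 without infested replicates 1, 2 and 3; with a 3' minus 5' covariate it was 11, and 636 when only the groups of the contrast were fitted. Of the 20 named genes 1 passed with the covariate, 8 unscaled, 0 without uninfested replicate 1 or infested replicate 1, and 7 without infested replicate 2 or 3.

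The resistant cultivar showed almost no called response to aphids on either day. On day 1 limma called 0 probe sets (2865 at an unadjusted p under 0.05, where 1880 are expected). The genes of smallest p had MET2 at −1.07 ± 0.28, GDH1 at −1.15 ± 0.30, SDP1-3 at −0.996 ± 0.28, NHX1 at 0.49 ± 0.14 and BZIP110 at −1.02 ± 0.29 (adjusted p = 0.62 for each, n = 3). The uninfested mean of NHX1 (5.35) lay near the 5th percentile of all values (5.28) and is not shown to be above background, so its difference is not an exact size. The phloem markers had a median of 0.45 (adjusted p = 0.0654), and no list was called on day 1 in this cultivar. In 9.66% of probe sets the groups did not overlap, against 10% by chance. The unscaled median shift was −0.145, and the count was 4 without infested replicate 3 and 1 without uninfested replicate 1. The infested arrays here were the least alike of any group, with a mean correlation of 0.957 among them. On the first principal component they scored 23.1, 66.2 and −12.5, and the uninfested ones −17.5, −7.22 and 22.6. With the replicate 3 arrays of both groups exchanged, 309 probe sets were called. The 0 calls therefore do not show that a response was absent.

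On day 7 limma called 1 probe set in the resistant cultivar (1070 at an unadjusted p under 0.05). It is Gma.10080.1.S1_at, which has no gene name and was chosen after its values were seen; it rose 3.69-fold (log2 1.88 ± 0.26, 8.47 ± 0.25 against 6.59 ± 0.38, SD, n = 3, adjusted p = 0.0188). SCOF-1 had 1.68 ± 0.45 (9.45 ± 0.39 against 7.78 ± 0.44), SPK-4 −0.75 ± 0.19, HPS 0.43 ± 0.12, PIP2-6 0.88 ± 0.28 and PTOX 0.43 ± 0.14, each with adjusted p = 1; the uninfested means of HPS (5.16) and PTOX (5.01) lay below the 5th percentile of all values (5.28). The 7 phenylpropanoid entry genes were higher as a set (median 0.61, 7 of 7 above 0, adjusted p = 0.000289; adjusted p = 0.897 with an estimated correlation). None passed singly and 1 rose when adjusted over the list alone, with PAL2.1 at 1.25 ± 0.40 and 4CL1 at 1.16 ± 0.46. This list was lower in the day 7 cultivar difference (median −0.88) and in the resistant day difference (−1.01). Both use the same uninfested resistant arrays of day 7, so these calls are not separate evidence. Replicate 1 of those arrays had a mean correlation of 0.933 with the others, where arrays ranged from 0.900 to 0.966. Flavonoids and isoflavonoids were higher as a set (median 0.59, 11 of 13 above 0, adjusted p = 0.0203; adjusted p = 0.916 with an estimated correlation), with IFS1, for isoflavone synthase, at 1.10 ± 0.48 and 0 of 13 passing, also when adjusted over the list alone. In 7.43% of probe sets the groups did not overlap, against 10% by chance. The call count was 8 unscaled, 0 with normexp background correction, 3 with the 3' minus 5' covariate, 0 without infested replicate 1, infested replicate 3 or any 1 of the 3 uninfested replicates, and 2 without infested replicate 2.

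The difference between the cultivars in the aphid effect on day 7 was tested directly. PM3 had a resistant minus susceptible difference of −3.31 ± 0.52 (adjusted p = 0.0139, n = 3 arrays in each of 4 groups), and LHCP had 1.63 ± 0.29 (adjusted p = 0.0175). SPK-4, a protein kinase gene, had −2.16 ± 0.27 and the calmodulin gene SCAM-5 had −1.59 ± 0.21 (adjusted p = 0.00331 for both), and BZIP71 had −2.37 ± 0.39. SCAM-5 in uninfested susceptible (5.23) and infested resistant leaves (5.27), and this probe set of PM3 in uninfested susceptible leaves (5.56), lay below or near the 5th percentile of all values (5.28) and are not shown to be above background, so their differences are not exact sizes. The phenylpropanoid entry genes differed as a set (median 1.44, 7 of 7 above 0, adjusted p = 0.00102; adjusted p = 0.656 with an estimated correlation); in it PAL2.1 passed (2.76 ± 0.57, adjusted p = 0.0351) and 4CL4 had 1.89 ± 0.64, with 5 of 7 passing when adjusted over the list alone. Fatty acid desaturation differed as a set (median 0.94, adjusted p = 0.0321, and adjusted p = 0.656 with an estimated correlation). FAD6.1 had 1.68 ± 0.42 and FAD8.2 had 2.07 ± 0.58, with 0 of 8 passing and 4 when adjusted over the list alone. This contrast holds the uninfested day 7 arrays of the cultivar difference with the opposite sign. In that difference the medians were −0.88 (phenylpropanoid entry) and −0.95 (desaturation). Reversed signs can follow from this sharing alone, so both list calls are not separate evidence. limma called 254 probe sets, 105 above and 149 below 0; unscaled values gave 17 and 480 with a median shift of −0.249, and centred values 189 and 252 with a shift of 0.113. The count was 880 with the 3' minus 5' covariate and 0 when only the 4 groups of the contrast were fitted. Without 1 array it was 12, 618 and 101 (infested resistant replicates 1, 2 and 3), 12 and 640 (uninfested resistant 1 and 3), 45 and 121 (infested susceptible 1 and 3), and 21, 400 and 14 (uninfested susceptible 1, 2 and 3).

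On day 1 the aphid effect of ADR11 differed between the cultivars by 3.96 ± 0.80 (adjusted p = 0.0422), that of BZIP48 by 3.30 ± 0.65 (adjusted p = 0.0406) and that of BZIP130 by −1.31 ± 0.23 (adjusted p = 0.0305). ALDH3J2, an aldehyde dehydrogenase gene, had 2.05 ± 0.42 and CHI3A1, for a chalcone isomerase, had 1.44 ± 0.30 (adjusted p = 0.0422 for both). In uninfested resistant leaves BZIP48 (5.50) and CHI3A1 (5.56) lay near the 5th percentile of all values (5.28) and are not shown to be above background, so their differences are not exact sizes. As sets, WRKY factors (median −0.56, adjusted p = 0.000349) and jasmonate synthesis (median −0.71, adjusted p = 0.0344) lay below 0, and desaturation (median 0.53, adjusted p = 0.016) and the phloem markers (median 0.98, 8 of 8 above 0, adjusted p = 0.00237) above it. All 4 had adjusted p = 0.668 with an estimated correlation, and jasmonate synthesis was not called with median centring (adjusted p = 0.0552). Among their members WRKY22 passed (−0.94 ± 0.22, adjusted p = 0.0473), while LOX9 had −2.58 ± 0.87, FAD8.2 2.21 ± 0.58 and SEOF 2.09 ± 0.72. When adjusted over the list alone, 2 WRKY genes, 0 of jasmonate synthesis, 4 of desaturation and 4 phloem markers passed. This contrast holds the uninfested day 1 arrays of the cultivar difference with the opposite sign. In that difference the medians were 0.58 (WRKY), −0.52 (desaturation) and −1.11 (phloem markers). Medians of reversed sign can follow from this sharing alone, so the list calls are not separate evidence. limma called 333 probe sets, 238 above and 95 below 0, while unscaled values gave 0 above and 11 below. The count was 0 with the 3' minus 5' covariate, 0 above the median brightness and 0 when only the 4 groups of the contrast were fitted. Without 1 array it was 170, 0 and 3775 (infested resistant replicates 1, 2 and 3), 1, 0 and 1669 (uninfested resistant 1, 2 and 3), 0 for each infested susceptible replicate, and 4 and 1398 (uninfested susceptible 1 and 2).

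The aphid effect of day 7 was set against that of day 1 within each cultivar. In the susceptible cultivar EXP2 had a difference of −2.10 ± 0.39 and PM3 of 2.80 ± 0.52 (adjusted p = 0.089 for both, n = 3 arrays in each of 4 groups), SPK-4 had 1.21, NAC19 1.38 and SCAM-5 0.91; the uninfested day 7 means of PM3 (5.56) and SCAM-5 (5.23) lay near or below the 5th percentile of all values (5.28), so neither difference is an exact size. limma called 0 probe sets (5928 at an unadjusted p under 0.05); the unscaled count was 7, with a median shift of 0.392. It was 2011 with array weights, 90 when only the 4 groups of the contrast were fitted, and it was 117 without infested day 7 replicate 2, 21 without uninfested day 1 replicate 2 and 2 without uninfested day 7 replicate 2. In the resistant cultivar limma called 0 (1032 at an unadjusted p under 0.05), with an unscaled median shift of 0.159. The 5 genes of smallest p there were SCAM-5 (−0.70), HPS (0.54), FAD8.2 (−0.55), UR2 (0.55) and TBP1 (0.39), each with adjusted p = 1. SCAM-5 (5.27) and FAD8.2 (5.43) in infested and HPS (5.16) in uninfested resistant leaves of day 7 are not shown to be above background, so these differences are not exact sizes.

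Between the 2 days the susceptible cultivar's calls overlapped. Of its probe sets, 83 rose on both days where 12.6 would by chance, 27 fell on both (11 by chance), 3 rose on day 1 and fell on day 7 (5.79 by chance) and 0 did the reverse (24 by chance). SCOF-1 and B13-1-9 rose and SGlu2 fell on both days. In the other fits that follow, same-sign overlaps were summed over all pairs of the 4 aphid effects, so resistant calls can enter. The overlap of 110 became 0 without uninfested day 1 replicate 1, 1, 56 and 38 without infested day 1 replicates 1, 2 and 3. It was 73 without uninfested day 1 replicate 3, 49 and 71 without infested day 7 replicates 1 and 3. It was 70 and 52 without uninfested day 7 replicates 1 and 3. It was 204 and 169 without infested resistant day 1 replicates 2 and 3, and 6 with the 3' minus 5' covariate. Across all probe sets, which are not independent replicates, the fold changes of both days correlated at r = 0.317 in the susceptible and 0.245 in the resistant cultivar.

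Among named genes that differed between uninfested leaves of the cultivars on both days, 8 were higher and 8 lower in resistant leaves. Rsv4 (LOC100812666), a locus named for resistance to soybean mosaic virus, was 7.15-fold higher in resistant leaves on day 1 (2.84 ± 0.21, SE, n = 3, adjusted p = 2.22e-07) and 8.14-fold on day 7 (3.03 ± 0.21, adjusted p = 1.05e-07). On both days DREB2 (LOC732579) was higher by 1.26 and 1.42 (SE 0.30), WRKY22 by 1.19 and 1.02 (SE 0.19), BZIP130 by 1.30 and 0.77 (SE 0.16), PAP25 by 1.08 and 1.16 (SE 0.23) and VAMP721D by 1.06 and 0.89 log2 units (SE 0.13). PBS1-2 (LOC100305406) was higher by 0.73 and 0.69 and bZIP129 (LOC778142) by 0.69 and 0.71. On day 1 the difference was called in 1 of 3 probe sets of VAMP721D and 1 of 2 each of DREB2 and bZIP129. It was called in 4 of 5 of WRKY22 and 3 of 3 of PAP25. EXP2 was lower by 1.35 on day 1 and had −2.175 on day 7 (SE 0.35), FAD8.2 was lower by 1.86 and 1.66 (SE 0.41), and AG1 by 1.58 and 1.89 (SE 0.36). SGF14n was lower by 1.78 and 1.48 (SE 0.35), PIP2-4 by 1.28 and 1.68 (SE 0.34) and MET2 by 1.03 and 1.47 (SE 0.28). MDH-1 was lower by 0.71 and 0.66 and PHR20 by 0.58 and 0.78. On day 7, 4 of these 16 genes passed without uninfested resistant replicate 1 or uninfested susceptible replicate 3, and 6 without uninfested susceptible replicate 1. In total 172 probe sets were higher in resistant leaves on both days (45.5 by chance), 144 lower (33.8 by chance) and 2 changed sides.

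Of the fixed lists on day 1, 15 of 53 WRKY genes were higher in resistant leaves (16 when adjusted over the list alone), among them WRKY54 by 1.64 ± 0.36. The set was higher (median 0.58, 47 of 53 above 0, adjusted p = 6.44e-05; adjusted p = 0.586 with an estimated correlation). Of the 8 phloem markers 6 were lower (7 when adjusted over the list alone), among them SEOA (−2.16 ± 0.46) and SEOF (−2.33 ± 0.51), and the set was lower (median −1.11, adjusted p = 6.44e-05; adjusted p = 0.422 with an estimated correlation). In the desaturation list FAD8.2, FAD3B (−1.30 ± 0.33), FAD3C (−1.74) and FAD2-3 (−0.65) were lower, 4 of 8 and also 4 when adjusted over the list alone, and the set was lower (median −0.52, adjusted p = 0.00621; adjusted p = 0.422 with an estimated correlation). In jasmonate synthesis 4 of 15 were higher, here named after their values were seen, LOX10 by 3.33, LOX1.4 by 2.49, AOS2 and LOX9, and among salicylate and PR proteins PR10 (2.39) and PAD4 (1.16); neither set was called (adjusted p = 0.14 for both). On day 7 phenylpropanoid entry (median −0.88, with PAL2.1 lower by 1.66, and 2 of 7 lower when adjusted over the list alone), desaturation (median −0.95, with FAD8.2 lower, and 4 of 8 when adjusted over the list alone) and the phloem markers (median −0.59, 0 of 8 passed, 3 when adjusted over the list alone) were lower as sets. All 3 had adjusted p = 0.00922, and adjusted p = 0.835 with an estimated correlation.

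For the cultivar difference limma called 7027 probe sets on day 1, 3348 higher and 3679 lower in resistant leaves, and 856 on day 7, 511 higher and 345 lower. The groups did not overlap in 39.6% and 23% of probe sets, against 10% by chance. Unscaled values gave 3670 higher and 747 lower on day 1, with a median shift of 0.204, and 232 higher and 107 lower on day 7. The day 1 count was 2240 without uninfested susceptible replicate 1, 3059 and 3124 without uninfested resistant replicates 1 and 2, and 1024 with the 3' minus 5' covariate, where 4 of the 16 named genes passed. The day 7 count was 115 and 556 without uninfested resistant replicates 1 and 2, and 180 and 161 without uninfested susceptible replicates 1 and 3. It was 1393 with the covariate and 146 when only the groups of the contrast were fitted.

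**Figure D3:**
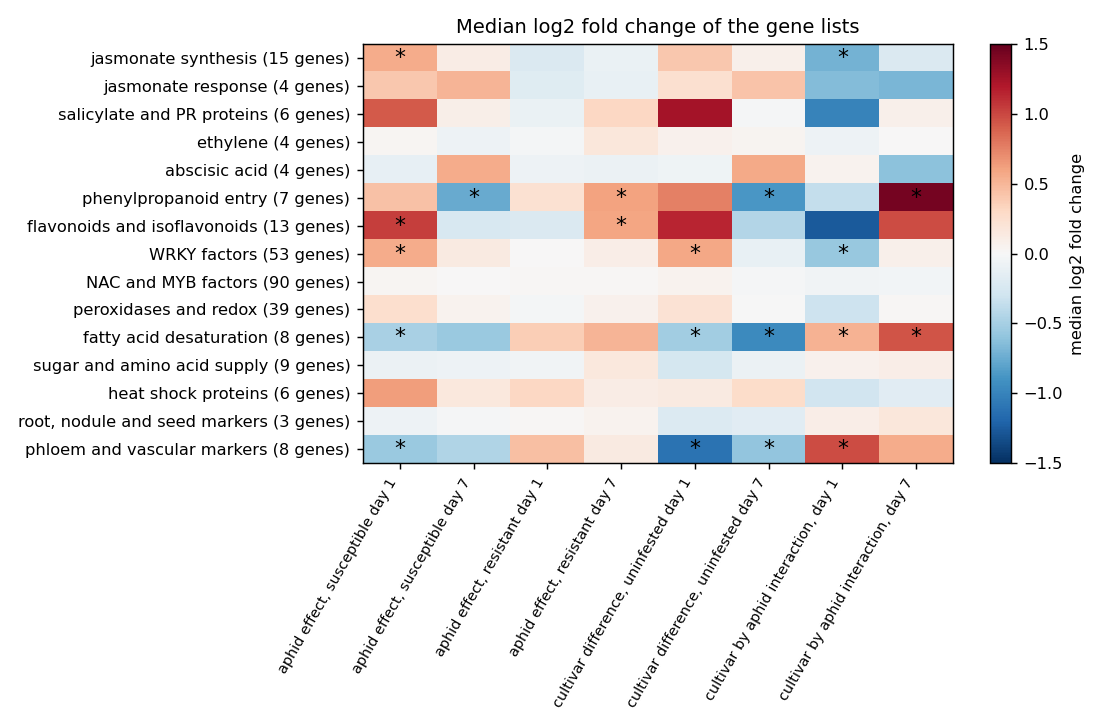
Median log2 difference of the members of each of the 15 tested fixed lists in 8 contrasts, with an asterisk where the adjusted p was under 0.05 at the preset correlation. The phloem markers had medians of −0.56, −1.11 and 0.98 in the day 1 contrasts of the susceptible aphid effect, the cultivar difference and the difference between cultivars in the aphid effect. These contrasts share the uninfested susceptible arrays of day 1, so their medians are not separate evidence.

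The remaining fixed lists were not called in any of the 8 planned contrasts or in the day differences. Their smallest adjusted p was 0.343 for jasmonate response, 0.0894 for salicylate and PR proteins (susceptible day 1, median 0.93), 0.729 for ethylene, 0.316 for abscisic acid, 0.27 for NAC and MYB factors, 0.0894 for peroxidases and redox (susceptible day 1, median 0.26), 0.305 for sugar and amino acid supply, 0.215 for heat shock proteins and 0.675 for root, nodule and seed markers.

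Uninfested leaves also differed between the days. In resistant leaves PAL2.1 was lower on day 7 by 1.85 ± 0.40 (adjusted p = 0.0137, n = 3), and phenylpropanoid entry was lower as a set (median −1.01, adjusted p = 0.00522; adjusted p = 0.756 with an estimated correlation), with 4 of 7 lower when adjusted over the list alone. Among WRKY genes WRKY22 (0.77) and WRKY51 (1.02) were higher and 5 of 53 were lower, WRKY16 (−1.28 ± 0.24) and WRKY55 (−1.73 ± 0.35) among them (2 and 11 when adjusted over the list alone). The set was lower (median −0.25, unscaled −0.403, adjusted p = 0.00522; adjusted p = 0.756 with an estimated correlation). In susceptible leaves the phloem markers were lower on day 7 as a set (median −0.77, adjusted p = 0.00688; adjusted p = 0.584 with an estimated correlation), with SEO-F3 at −0.99 ± 0.36, 0 of 8 passing and 4 when adjusted over the list alone. limma called 3946 probe sets in susceptible leaves, 1961 higher on day 7 and 1985 lower (unscaled 417 and 177), and 1469 in resistant leaves, 752 and 717 (unscaled 238 and 722, median shift −0.119). The groups did not overlap in 31.3% and 23.8% of probe sets, against 10% by chance. The susceptible count was 233 and 1217 without day 7 replicates 2 and 1, and 313 without day 1 replicate 1. It was 479 with the 3' minus 5' covariate and 10 when only the groups of the contrast were fitted. The resistant count was 783, 320 and 929 without day 1 replicates 1, 2 and 3, and 340 without day 7 replicate 1.

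The genes that changed with aphids in susceptible leaves on day 7 were compared with those that differed between the cultivars without aphids. Across the 1067 called probe sets, which are not independent replicates, the aphid effect correlated with the cultivar difference of day 1 at r = 0.541 (Spearman's rho 0.533), and 79.3% had the same sign; these contrasts share no arrays. EXP2, PIP2-4 and AG1 fell with aphids and were lower in uninfested resistant leaves, and DREB2 rose and was higher there. Of called probe sets 123 were higher in both (65.1 by chance), 121 lower in both (32.9 by chance), and 4 and 2 went opposite ways. Across all probe sets r was 0.356, and unscaled values gave 0.111 for the called ones. Leaving out 1 array moved r between 0.402 (uninfested susceptible day 7 replicate 3) and 0.619 (uninfested resistant day 1 replicate 3). Against the cultivar difference of day 7, which shares the uninfested susceptible arrays, r was 0.75 across the called and 0.783 across all probe sets. Simulated arrays with the same sharing and no effect gave 0.5 across all probe sets, with a covariance of 0.027 against the observed 0.149, a difference of 0.122.

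**Figure D4:**
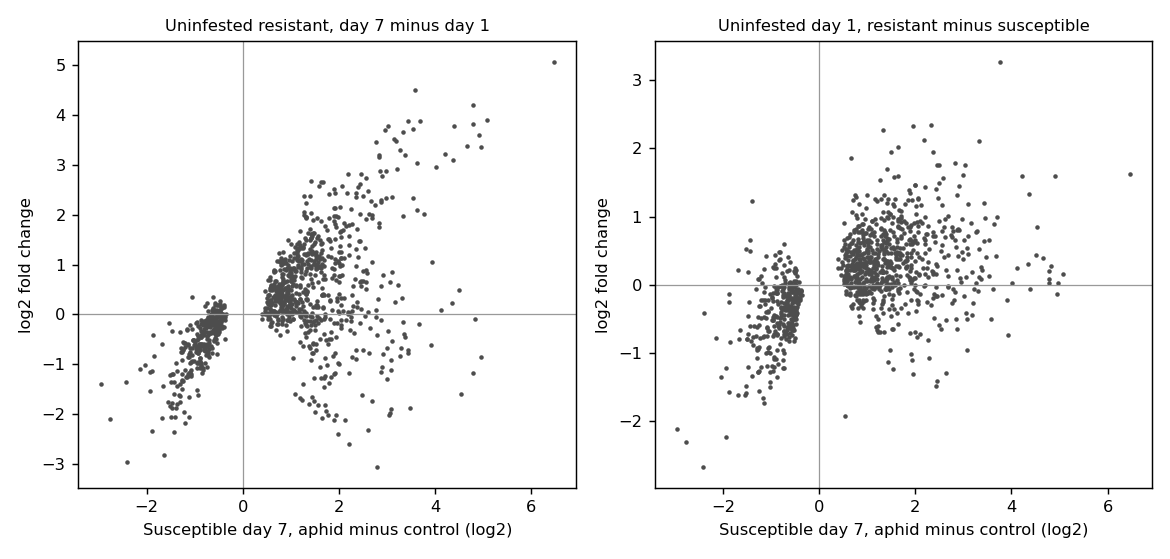
Log2 aphid effect of the 1067 probe sets called in susceptible leaves on day 7 (horizontal axis) against their day difference in uninfested resistant leaves and against their cultivar difference on day 1 (vertical axes). Across these probe sets r was 0.554 and 0.541.

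The same 1067 probe sets were compared with the change from day 1 to day 7 in uninfested resistant leaves. There r was 0.554 (rho 0.53) with 80.7% of the same sign; 211 probe sets were higher in both (14.6 by chance) and 84 lower in both (6.41 by chance), while 32 rose with aphids and were lower on day 7 (13.9 by chance) and 0 did the reverse (6.72 by chance). PM3, among them, was higher by 1.84 ± 0.46 in uninfested resistant leaves on day 7 (adjusted p = 0.0275). Its values there were 9.04, 7.06 and 7.35 on day 7, the highest on replicate 1. On day 1 they were 6.27, 5.90 and 5.75, levels not shown to be above background. Against the aphid effect in resistant leaves on day 7, r was −0.02 with 31.2% of the same sign. Across all probe sets it was −0.29 (rho −0.406), and 0.06 without uninfested resistant day 7 replicate 1.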

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

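The tests of array brightness and of younger leaves were chosen only after the results were seen, as were the fits with a 3' minus 5' covariate.

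The aphid effect differed between the cultivars in 333 probe sets on day 1 by the test of the difference itself. By the same test BZIP130 (−1.31), BZIP48 (3.30), ADR11 (3.96), ALDH3J2 (2.05) and CHI3A1 (1.44) differed on day 1, as resistant minus susceptible log2 values. The lists of jasmonate synthesis (median −0.71), WRKY factors (−0.56), fatty acid desaturation (0.53) and phloem markers (0.98) differed on day 1 at the preset correlation, and none did with an estimated one (adjusted p = 0.668 for each). On day 7 the effect differed in 254 probe sets, with SPK-4 at −2.155, SCAM-5 at −1.59, PM3 at −3.31, BZIP71 at −2.37 and LHCP at 1.63. The values of SCAM-5, PM3, BZIP48 and CHI3A1 are not exact sizes, since group means of SCAM-5 (5.23 and 5.27), PM3 (5.56), BZIP48 (5.50) and CHI3A1 (5.56) lay below or near the 5th percentile of all values (5.28) and are not shown to be above background. The lists of phenylpropanoid entry (1.44) and fatty acid desaturation (0.94) differed on day 7 at the preset correlation, with adjusted p = 0.656 for both with an estimated one. The list medians of both days can follow from uninfested arrays shared with the cultivar differences, so they are not separate evidence. The 60 control probe sets enter no count of calls, though their 3' minus 5' signal is the covariate above. Among them the 3' probe set of the control transcript SucBP was lower in infested than in uninfested susceptible leaves on day 1 (log2 −1.82, adjusted p = 0.0479), and it was the 1 control probe set called there. It was also called in the day difference of uninfested susceptible leaves (−1.67, adjusted p = 0.0448). In the day 1 cultivar difference 5 of the 60 were called, all lower in resistant leaves: SucBP 3' (−1.71) and 4 actin probe sets (−0.615 to −1.09). SucBP is part of the 3' minus 5' signal and so of the covariate. Its 5' probe set had −0.042 in the day 1 susceptible aphid effect, 0.011 in the susceptible day difference and −0.169 in the day 1 cultivar difference. Whether RNA quality or the level of that transcript moved its 3' probe set was not tested.

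Uninfested susceptible leaves of day 1 stood apart from the other groups, and the simple contrasts that use them had the most calls (1883, 7027 and 3946). Unequal array brightness was not decided: 0 of their 3 deposited medians (7.833, 7.14 and 7.484) lay outside the range of the other arrays. That range holds both extremes of the series (7.00 and 8.04), so the check shows only that these arrays were not the brightest or dimmest. Younger leaves stay open: across probe sets, which are not independent replicates, the susceptible aphid effect of day 1 and the day difference in uninfested resistant leaves correlated at r = 0.004, while the day differences of both cultivars correlated at r = 0.267. RNA quality stays open too: with a 3' minus 5' covariate the median ratio of log2 differences to those without it was 0.735 in the day 1 cultivar calls and 0.722 in the aphid effect, against 1.032 in the aphid effect on day 7, and the median absolute cultivar difference went from 0.806 (SE 0.209) to 0.598 (SE 0.225). A state of these 3 plant samples, including their phloem marker level of 7.16, may also set the group apart. Single arrays did not part this from RNA quality. The 3' minus 5' signal was 1.721 on replicate 1 of the group, and 1.005 and 1.205 on replicates 2 and 3. Infested resistant day 1 replicate 2 had 1.504 and scored 66.2 on the first principal component. Infested susceptible day 7 replicate 3 had 1.385 and scored −46.9.

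Across probe sets the aphid effect in susceptible leaves on day 7 correlated with the change from day 1 to day 7 in uninfested resistant leaves at r = 0.522. With the 3' minus 5' covariate r was 0.504. That signal averaged 1.175 in infested and 0.935 in uninfested susceptible leaves of day 7. In uninfested resistant leaves it averaged 0.933 on day 7 and 0.833 on day 1. The fit thus had little to adjust and does not decide on RNA quality, which stays open. A single unusual array stays open: without uninfested resistant day 7 replicate 1, r was 0.384, and leaving out each array in turn gave 0.384 to 0.577. Without that array the correlation between the susceptible and resistant aphid effects on day 7 went from −0.29 to 0.06. A stress-like state of uninfested resistant leaves on day 7 may be a biological source, and it was not tested apart from that array.

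Cultivar differences of the same sign on both days may reflect sequence differences under single probe sets, which change binding without a change in level. Other probe sets of the same genes carried a median share of 0.671 of the cultivar difference, against 0.684 for the susceptible aphid effect on day 7, a difference of −0.013 whose bootstrap interval (−0.247 to 0.222, from 46 and 180 probe sets) is too wide to decide. Clustering along the chromosomes, as a region bred into 1 cultivar would give, also stays open. Among the 6010 measured genes placed in order, 1 pair next to each other was called, Rsv4 and LOC100526921. Unmeasured genes may lie between them, and their differences had opposite signs (2.84 and −6.72 on day 1, 3.03 and −7.33 on day 7). For such pairs 10000 random placements gave a median of 0 and an upper bound of 3 (one-sided permutation p = 0.468). A true difference in expression between the cultivars stays open too.

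Relabelled samples were counted for each contrast. For contrasts of 3 against 3 arrays the 10 splits are too few for a share under 0.05. In the susceptible aphid effect 1 of 10 splits gave as many calls as the real one on day 1 (1883 real, 0 highest other) and 1 of 10 on day 7 (1067 real, 1 highest other). In the cultivar difference 1 of 10 did on day 1 (7027 and 0) and 1 of 10 on day 7 (856 and 0), and in the day difference 1 of 10 in susceptible (3946 and 0) and 1 of 10 in resistant leaves (1469 and 0). In the resistant aphid effect on day 7, 2 of 10 did (1 real, 36 highest other). On day 1 the real count was 0, so 10 of 10 splits give as many by construction and the count says nothing about chance; the highest other split, exchanging the replicate 3 arrays, called 309.

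For the difference between cultivars in the aphid effect, 3 of 100 splits gave as many calls on day 1, a share under 0.05. The splits exchanged infested and uninfested labels within each cultivar, so they model no aphid effect in either cultivar. They do not model an equal effect in both, so that share cannot exclude chance. They also take no account of replicate numbers, and the call is lost in other fits, so chance is left open here. The real count of 333 became 98 with a replicate block, 0 with a block within each day and 0 when only the contrast's own groups were fitted. The highest other split, which exchanged the replicate 3 arrays of infested and uninfested resistant leaves, called 5103 and the next 849 against the real 333. The susceptible arrays kept their real groups in the 5103 split, so its calls can include the susceptible aphid effect. It may also reflect a structure of the resistant samples other than the groups, which was not tested. On day 7, 5 of 100 did, so chance cannot be excluded (254 real). The highest other split exchanged infested replicate 2 with uninfested replicate 3 of resistant leaves and called 2140. The susceptible arrays kept their real groups there too, so the same limit applies. For the difference between days in the aphid effect the real count was 0 in both cultivars, so 100 of 100 splits give as many by construction and the count says nothing about chance; the highest other split called 3672 in susceptible and 459 in resistant leaves.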

How the results depend on the processing

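The unscaled values were the planned main choice and became an alternative only after seeing the data. Normexp correction, the 3' minus 5' covariate, leaving out 3 arrays, tests of lists against all genes and leaving out each array for the lists, overlap and constitutive comparison were chosen only after seeing the data. Named genes kept their direction in all 1927 combinations of a gene, contrast and setting: 1522 stayed on their side of the threshold, 394 no longer passed and 11 newly passed. Called lists did so in all 660 combinations of a list, contrast and setting, with 568 on their side and 92 not. The genes and lists were picked from these same arrays, which favours a kept direction, so it is no separate support. The counts of calls did change much, with single arrays, weighting, scaling, the 3' minus 5' covariate and the groups fitted. The cause was not tested except where fewer probe sets, genes or arrays entered by construction. With no background estimate, signal over background is unknown.

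Below, S1 and S7 stand for the aphid effect in susceptible leaves on days 1 and 7, R1 and R7 for that in resistant leaves, I1 and I7 for its difference between cultivars, TS and TR for the day difference in uninfested susceptible and resistant leaves, C1 and C7 for the cultivar difference in uninfested leaves, and DS and DR for the difference between days in the aphid effect. Median centring gave I7 441. Probe sets above the median brightness gave I1 0 and C1 4537. A trended, robust variance gave I1 193. Array weights gave S1 4857, S7 2660, I1 2173, I7 880, DS 2011, C1 11448, C7 2349, TS 7019 and TR 4595. A minimum of 2-fold gave S1 777, S7 603, C1 2456, C7 468, TS 1263 and TR 827. Fitting only the groups of a contrast gave S1 636, R7 2, I1 0, I7 0, DS 90, C7 146 and TS 10. Unscaled values gave S1 151, S7 2137, R7 8, I1 11, I7 497, DS 7, C1 4417, C7 339, TS 594, TR 960 and a constitutive correlation of 0.111. Normexp gave R7 0. The 3' minus 5' covariate gave S1 11, S7 2362, R7 3, I1 0, I7 880, C1 1024, C7 1393, TS 479 and an overlap of the aphid effects of 6. Without uninfested susceptible day 1 replicate 1, uninfested resistant day 7 replicate 1 and infested resistant day 1 replicate 2, whose mean correlations with the others were lowest (0.900, 0.933 and 0.942), the counts were S1 339, S7 2147, R7 0, I1 4, I7 75, DS 61, C1 3692, C7 205, TS 1417, TR 710, 9 lists and an overlap of 58. Summed over all pairs of the 4 aphid effects, resistant ones included, the same-sign overlap at an unadjusted p under 0.05 was 2362. It is not that of the susceptible effects alone. Of 20 list calls, 0 held with an estimated correlation; 34 were made over all probe sets, and fry, which does not compare a list with other genes, called 3. The constitutive correlation was 0.75 with day 7 controls shared and 0.356 over all probe sets.

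Leaving out 1 array at a time gave S1 9 to 2913, S7 222 to 1250, R1 0 to 4, R7 0 to 2, I1 0 to 3775, I7 12 to 640, DS 0 to 117, DR 0 to 1, C1 2240 to 7127, C7 115 to 1111, TS 233 to 4890, TR 320 to 1426, lists 15 to 22, overlap 0 to 204 and the constitutive correlation 0.402 to 0.619. The jackknife SD of that correlation over 12 arrays was 0.239.

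By the rule that each pair's correlation be over 0.1, replicate numbers were not treated as pairs, but the numbers carried some shared structure, of which the labels give no source. Residuals of arrays with the same number correlated at 0.079 on average (84 pairs) against −0.039 for others (168 pairs), with a range of −0.499 to 0.457 for the former (one-sided permutation p = 0.0125 over 100000 exchanges of numbers within groups, chosen after seeing the data). Of 24 arrays 13 were closest to their own number, where chance gives 8, and replicate 1 lay above replicate 3 on the third principal component in 8 of 8 groups. For the aphid effect in susceptible leaves on day 7 all 3 pairs were above 0 (0.071 to 0.386). A replicate block gave R7 7, I1 98, I7 384 and an overlap of 169, and a block within each day gave R7 6 and I1 0.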

Other observations

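The 20 lists below were added after the annotation's symbols were read, and the list tests for the day differences were added after the results were seen.

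In susceptible leaves infested for 7 days, 7 of 32 late embryogenesis and maturation genes rose and the rest did not pass; besides PM30, MAT1, PM35 and PM3 these were PM29 (1.98 ± 0.43, SE, n = 3), PM9 (1.92) and MP2 (1.59). As a set they were higher (median 0.44, unscaled 0.68, 29 of 32 above 0, adjusted p = 3.31e-06; adjusted p = 0.48 with an estimated correlation), and 13 rose when adjusted over the list alone. Of 7 genes for DREB factors, which act in drought and cold responses, 4 rose: the DREB1-like gene, DREB2A2 (1.67 ± 0.35), DREB2 (1.44 ± 0.30) and DREB3 (0.79). That set was higher too (median 1.09, adjusted p = 0.000552; adjusted p = 0.204 with an estimated correlation), as were the NAC factors (median 0.80, adjusted p = 0.000326; adjusted p = 0.48 with an estimated correlation), with NAC1 passing. The protease inhibitor genes BBI-1 (2.02) and CYSTATIN (0.97) rose, while their set was not called (adjusted p = 0.175). On day 1 the NAC factors were higher as a set (median 0.96, adjusted p = 0.0166; adjusted p = 0.753 with an estimated correlation), where 0 of 20 passed and 7 rose when adjusted over the list alone. The late embryogenesis (median −0.52, adjusted p = 1.75e-05; with PM3 at −3.32 ± 0.65 by its brightest probe set), DREB (−1.30, adjusted p = 0.0106) and NAC sets (−0.59, adjusted p = 0.0106) differed between the cultivars in the day 7 aphid effect. With an estimated correlation their adjusted p was 0.438, 0.371 and 0.488, and the unscaled median of the NAC set was −0.973. That contrast holds the susceptible arrays of day 7 with the opposite sign, so these calls are not separate evidence.

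Between uninfested leaves on day 1, 8 of 16 aquaporin genes, which encode water channels, were lower in the resistant cultivar, PIP1-6 at −3.88 ± 0.70 and PIP1-4 at −1.40 ± 0.25 (SE, n = 3); the set was lower (median −0.74, adjusted p = 0.000594; adjusted p = 0.463 with an estimated correlation). NAC factors were higher (median 0.86, adjusted p = 0.00752; adjusted p = 0.693 with an estimated correlation), NAC34 by 2.52 and NAC26 by 2.42 among 5 that passed. In the day 1 aphid effect these sets differed between the cultivars too, aquaporins with a median of 0.43 (PIP1-6 at 4.27 ± 0.99) and NAC factors with −0.79 (adjusted p = 0.0111 for both, and 0.72 with an estimated correlation). That contrast holds the same uninfested day 1 arrays with the opposite sign. Medians of reversed sign can follow from this sharing alone, so they are not separate evidence. On day 7 protease inhibitors (median 0.26, adjusted p = 0.0248, with BBI-1 at 2.03 ± 0.51) and late embryogenesis genes (median 0.40, adjusted p = 0.000578, with PM3 at 1.90) were higher in uninfested resistant leaves, with adjusted p = 0.296 and 0.638 with an estimated correlation. With median centring the protease inhibitors were not called there (median 0.118, adjusted p = 0.0934).

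In resistant leaves on day 7 the wider flavonoid pathway was higher with aphids (median 0.21, adjusted p = 0.00244; adjusted p = 0.331 with an estimated correlation; HIDH at 1.31 ± 0.58) and differed between the cultivars (median 0.48, centred 0.758, adjusted p = 0.0108; adjusted p = 0.438 with an estimated correlation). There protease inhibitors were lower as a set (median −0.14, adjusted p = 0.0412; adjusted p = 0.331 with an estimated correlation), a call lost under each other scaling (adjusted p = 0.297 centred, 0.0643 with normexp and 0.227 unscaled; medians −0.069, −0.094 and −0.061). The bZIP factors were lower as a set (median −0.04, adjusted p = 0.0404), a call that held with an estimated correlation (adjusted p = 0.0434), though 0 of 65 passed singly. In uninfested resistant leaves the late embryogenesis set was higher on day 7 than on day 1 (median 0.39, unscaled 0.211, adjusted p = 0.00361; adjusted p = 0.521 with an estimated correlation).

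LOC100526921, chosen after its values were seen, was lower in uninfested resistant leaves on both days (adjusted p = 1.79e-16 and 3.31e-17). Its means were 12.27 to 12.68 in the 4 susceptible groups and 5.36 to 5.55 in the 4 resistant ones, near the 5th percentile of all values (5.28), with or without aphids. It is not shown to be above background in resistant leaves, so no fold is given.

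The single probe set called in resistant leaves on day 7, Gma.10080.1.S1_at, was lower in uninfested resistant than in uninfested susceptible leaves that day (−2.00, adjusted p = 0.000394) and lower there on day 7 than on day 1 (−2.44, adjusted p = 0.000292). Its aphid effect on day 7 did not pass the test of the difference between cultivars (1.38, adjusted p = 0.0738). All these comparisons use the same uninfested resistant arrays of day 7 as the call that selected it, so they are not separate evidence.

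The other added lists were not called in the 8 planned contrasts or the 2 day differences, the contrasts in which lists were tested. Their smallest adjusted p was 0.172 for vegetative storage, 0.189 for the wider ethylene list, 0.0635 for cytochrome P450s, 0.273 for glutathione transferases, 0.0629 for MYB factors, 0.183 for heat shock factors and proteins, 0.0629 for the wider photosynthesis list, 0.0999 for calmodulins and CDPKs, 0.429 for immune regulators, 0.15 for PR and osmotin-like proteins, 0.398 for nitrogen and sucrose handling, 0.44 for seed and nodule genes and 0.17 for named cell wall genes.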
